A study of Mus musculus with 2 samples.

How the data were processed

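The series holds 2 libraries of mouse cells from LLC tumours, labelled as tumour-infiltrating lymphocytes, 1 from wild-type mice (WT) and 1 from mice without Dusp2 (KO). Per the labels' protocols both were made with the 10x Chromium Next GEM 3' kit, version 3.1. The labels give the molecule as total RNA for WT and polyA RNA for KO. Whether a library pools several animals, how the cells were sorted, and which part of Dusp2 was deleted are not given in the sources used here. The values are raw UMI counts per gene and cell barcode, deposited as matrices of 33696 genes. Per the submitters' processing notes the reads were processed with Cell Ranger 6.0.1 and Seurat 4.0.3 and 4.0.4 on mm10, while the matrices name Cell Ranger 8.0.1, per the file headers. The annotation release and the strand setting are not given in the sources used here. The barcodes are those the authors' cell calling kept.

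The WT library holds 9890 barcodes and 113873249 UMIs, the KO library 12744 and 101532711. Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, 9765 and 12636. Doublets were called per library with Scrublet through scanpy 1.11.5. Its automatic threshold called 128 WT cells (1.31%) and 0 KO cells. Where it calls under 0.5%, the rule fixed beforehand left out the highest scores at an expected rate that grows with the number of cells. That took 1277 KO cells (10.1%) and leaves the libraries with different doublet rates. The kept cells are 9637 WT with 111187671 UMIs and 11359 KO with 92517851 UMIs. Their medians are 2786 and 1920 genes per cell.

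Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes without mitochondrial, ribosomal protein, haemoglobin, Ig, TCR and sex-linked marker genes and without Dusp2 gave 30 principal components, 15 neighbours and Leiden clusters at resolution 1.0 over both libraries together, with seed 0 and no batch correction. This gave 34 clusters, and T-like cells were clustered again into 19 subclusters. Clusters were named among 14 classes, and T subclusters among 4, with marker lists fixed before the files were seen. A cluster took the class with the highest score if at least 3 of its markers were above the other cells and detected in 10% of cells, and the score was above 0.05, or 0.1 for T classes. No other class could have more markers among the 10 genes with the highest fold, and T classes needed a core gene in 30% of cells. A marker of the class itself among those 10 was needed only in clusters that were shallow or, outside the T subclusters, small. Cluster 26 and T subclusters 13 and 17 were named without one. The fold by geometric means, the T-level limits and the Y-positive group were chosen after the clusters were seen. Y-positive means at least 20 CPM of the Y-chromosome genes Ddx3y, Eif2s3y, Uty and Kdm5d together, met by 5 clusters. Names were given to all but 6 clusters and 8 T subclusters. Unnamed clusters hold 12.2% of WT and 14.1% of KO cells, or 4.51% and 4.21% outside the Y-positive clusters.

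Within a class the UMIs of each gene were summed per library and divided by all UMIs of the class, and scaled to CPM. Intervals are 95%, exact Poisson for a level, Clopper-Pearson for a share, and the matching exact interval for a ratio of levels. For a log2 ratio of shares the interval is a normal approximation. They cover counting error only. A side with 0 UMIs was given a floor of 3 UMIs and the ratio is written as at least that fold. With 1 library per genotype no test was made and no gene counts as changed. Shares of cells with a UMI were computed with all UMIs and with each cell thinned to 2000 UMIs, leaving out shallower cells.

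Named genes were taken by a fixed rule. Genes were ranked by the bound of their interval that is nearest 0, and those where this bound lies farthest from 0 are named. In CD8 T-like and monocyte/macrophage-like cells 12 per direction are named, and 4 in other classes of at least 100 cells per library. A candidate needs at least 50 UMIs in 1 library and a mean of 30 CPM, and is not a mitochondrial, ribosomal protein, haemoglobin, Ig, TCR or predicted gene. There were 4720 candidates in CD8 T-like and 4465 in macrophage-like cells, so the largest ratios are selected from many. Some genes that this rule or the lists name are not reported here. Dusp2, Pdcd1, Ifng, Gzmb, Nfatc1, Tcf7, Ifnar1 and Isg15 were fixed beforehand.

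All 22 gene lists were fixed before the files were seen, with 9 members found under another symbol. They cover inhibitory receptors and exhaustion, cytotoxic effectors, naive and memory genes, type I interferon response, interferon receptor and ligands, NFAT-linked genes, ERK and immediate-early genes, other dual-specificity phosphatases, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, MHC class I, MHC class II, regulatory T function, co-stimulatory receptors, alternatively activated and inflammatory macrophage genes, checkpoint ligands and suppressive enzymes, heat shock, haemoglobin, neutrophil and myeloid transcripts. A member counts as measured with at least 20 UMIs in the class over both libraries. The median log2 ratio has a half-width from 400 resamplings of counts. Its percentile comes from 10000 random lists, each member drawn from the 101 genes nearest in level. Lists share members and genes within a cell vary together, so percentiles are not p-values. All lists are reported in CD8 T-like and macrophage-like cells. In other classes only the interferon response, NFAT-linked and up to 2 further lists are reported, a restriction made after the values were seen, as was the choice of the results led with.

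The ratio and list steps were tested on simulated data drawn from the real levels with 200 genes changed. Each gene was drawn independently from a Poisson distribution, as the intervals assume. Real UMIs can pile up in 1 cell and real genes vary together, so this checks the calculation and not its fit to these data. In CD8 T-like cells (9613 genes) 96% of the intervals for changed genes held the true value and 6% of 200 unchanged lists fell outside percentiles 5 to 95. In macrophage-like cells (14724 genes) these were 97% and 9%, and a list made lower by 1 log2 unit lay at percentile 0 in both. To take off macrophage-like RNA, its share was estimated per library from Lyz2 and from the median of the macrophage markers. The larger, 1.77% in WT and 1.12% in KO CD8 T-like cells, was multiplied by each gene's macrophage-like level and subtracted, a step added after the marker medians were seen.

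Alternatives fixed beforehand were a stricter cell filter (500 genes, 10% mitochondrial), every barcode, doublets kept, resolutions 0.5 and 2, a marker score per cell without clusters, thinning before clustering, clustering without list genes, other CPM denominators, centring on the class median, list members with at least 5 or 100 UMIs, and the mean of each cell's CPM. Added later were the expected doublet rate in both libraries, arithmetic folds for naming, a denominator without B-like and plasma-like cells, leaving out the cell with the most UMIs of a gene, and subclusters 1 and 4 alone. Left out were cell trajectories, receptor clonotypes, cell-cell signalling and any per-animal comparison, for which the data hold no replicate or sequence. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with GENCODE M21 for gene positions, which holds 31961 of the gene IDs.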

Results

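Single-cell RNA was counted in tumours of LLC, a mouse Lewis lung carcinoma line, grown in wild-type (WT) mice and in mice lacking Dusp2 (KO). Dusp2 encodes a nuclear dual-specificity phosphatase that removes phosphate from MAP kinases and is induced early in activated T cells. The question behind the series is how type I interferon, Dusp2 and the transcription factor NFAT shape tumour-infiltrating immune cells. Each genotype is 1 library of 10x 3' RNA. The WT library holds 9890 barcodes and 113873249 UMIs, with a median of 8496 UMIs per barcode. The KO library holds 12744 barcodes and 101532711 UMIs, with a median of 4754. After cell and doublet filters 9637 WT and 11359 KO cells were kept, with medians of 8533 and 4852 UMIs.

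With 1 library per genotype, no difference below has a replicate check, and genotype cannot be told from animal, tumour size, dissection or library preparation. All intervals are 95% and cover counting error only. Levels are in CPM, the UMIs of a gene scaled to the same total of UMIs in each cell class, and log2 values are KO over WT, so a positive value is higher in KO. A gene list is summarised by the median log2 of its measured members. Its percentile is its place among 10000 random lists of genes of similar level, which is a description. Cell classes are named "like" a type because they rest on marker genes alone.

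Dusp2 itself was nearly absent from the immune cells of the KO library. The gene lies on mouse chromosome 2, plus strand, from base 127336159 to 127338376 (mm10/GRCm38, GENCODE M21), with 4 exons, and its 3' UTR starts at base 127337793 of the last exon. Outside the clusters that express Y-chromosome genes, Dusp2 stood at 173 CPM (170 to 177) in WT and 1.71 CPM (1.39 to 2.09) in KO, 101-fold lower, log2 -6.66 (-6.96 to -6.37). In CD8 T-like cells it was 582 (553 to 612) against 6.98 CPM (3.91 to 11.5), and 9 of the 15 KO UMIs came from 1 cell. NK-like cells held the most, 1108 (1073 to 1143) against 2.30 CPM (0.628 to 5.90). Levels were 236 against 1.80 CPM in conventional CD4 T-like cells, log2 -7.03 (-9.33 to -5.46) from 3 KO UMIs, 67.6 (65.2 to 70.0) against 1.75 (1.13 to 2.58) in monocyte/macrophage-like cells and 202 against 1.59 in conventional dendritic-like cells, log2 -6.99 (-10.04 to -5.13) from 2 KO UMIs. Regulatory T-like cells held 206 WT UMIs and 0 KO UMIs, at least 83.7-fold lower.

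Some 84.6% of WT and 1.62% of KO CD8 T-like cells carried a Dusp2 UMI, at median depths of 5310 and 3898 UMIs. With every cell thinned to 2000 UMIs the shares were 60.7% and 1.87%. In fibroblast-like cells, where little Dusp2 is known, the shares were 9.22% and 3.08% at depths of 7894 and 4688, and 2.5% and 0% after thinning. The Y-positive clusters, which include the tumour-like cells, together carried Dusp2 at 76.6 (74.1 to 79.2) against 77.4 CPM (74.6 to 80.4), log2 0.016 (-0.056 to 0.089). By cluster the ratio was 0.062 (-0.058 to 0.18) in cluster 4, 0.19 (0.058 to 0.33) in cluster 6, 0.26 (0.11 to 0.41) in cluster 9, -0.59 (-1.18 to -0.044) in cluster 26 and -0.97 (-4.12 to 1.08) in cluster 31. Over all kept cells this brought the values to 133 (131 to 136) against 30.6 CPM (29.5 to 31.8), log2 -2.12 (-2.18 to -2.06). The mouse is the knockout here, and the labels give no edit of the LLC line. The part of Dusp2 that was deleted is not given in the sources used here, so these UMIs do not say whether a 3' end without protein is left.

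**Figure D1:**
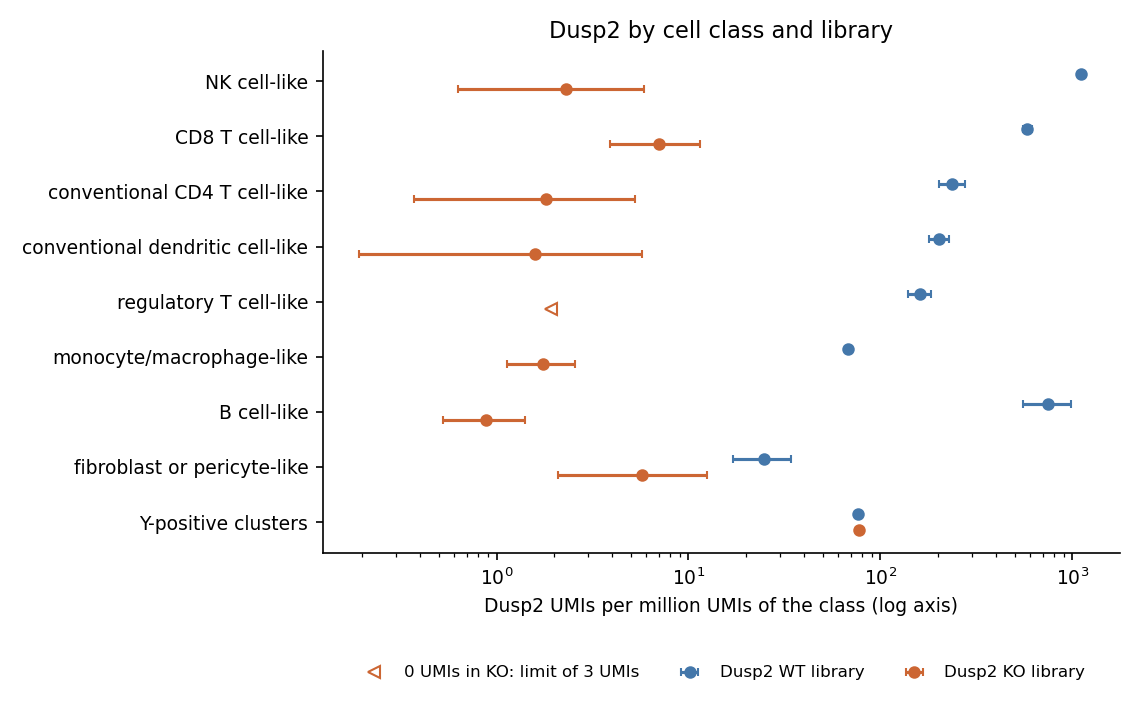
Dusp2 level in CPM (log axis) by cell class in the WT and KO libraries, 1 library each. Bars are 95% Poisson intervals that cover counting error only, and the open triangle marks 0 UMIs, drawn at the level of 3 UMIs.

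B-like cells made up 34.4% (33.5 to 35.3) of the KO library, 3904 cells, and 0.145% (0.0794 to 0.244) of the WT library, 14 cells. Plasma-like cells were 2.80% (2.504 to 3.12) of KO, 318 cells, and 0.0415% (0.0113 to 0.106) of WT, 4 cells, log2 6.08 and 4.07 to 8.11 over the alternative settings. Ig genes held 57.1% of their UMIs in KO but 0.00791% in WT, at medians of 6854 and 727 UMIs per cell, so the 4 WT cells do not show the antibody RNA of plasma cells. T-like cells were also a larger share of KO, 20.2% (19.4 to 20.9) against 13.8% (13.1 to 14.5), as were plasmacytoid dendritic-like cells, the main interferon-alpha producers, 1.04% against 0.270%, log2 1.94 (0.73 with the marker score per cell). Monocyte/macrophage-like cells were 53.4% (52.4 to 54.4) of WT and 17.6% (16.9 to 18.3) of KO, and NK-like cells 6.64% (6.15 to 7.16) and 3.02% (2.71 to 3.35). Conventional dendritic-like cells were 1.86% (1.60 to 2.15) and 1.76% (1.53 to 2.02), or log2 -0.61 with the marker score per cell, fibroblast-like cells 1.46% (1.23 to 1.72) and 1.14% (0.957 to 1.36), and neutrophil-like cells 0.467% and 0.326%. Tumour or epithelial-like cells were 9.76% and 3.73%, and all Y-positive clusters 17.4% and 13.6%. The first of these depends on naming, since Y-positive clusters 6 and 9, with 391 and 315 WT and 571 and 545 KO cells, scored highest for the same class but were left unnamed. The conventional dendritic-like class is cluster 16 alone. Cluster 11, with 414 WT and 351 KO cells, scored highest for that class too but was left unnamed. Shares sum to 100, so a large B-like share lowers the others. Among cells that were neither B-like nor plasma-like, macrophage-like cells were 53.5% and 27.9%, T-like cells 13.8% and 32.1%, and NK-like cells 6.65% and 4.81%. On that base conventional dendritic-like cells were 1.86% and 2.80%, log2 0.59 (0.30 to 0.88), and all Y-positive clusters 17.5% and 21.7%, log2 0.31 (0.22 to 0.40), both higher in KO. Fibroblast-like cells were 1.47% and 1.82%, neutrophil-like cells 0.468% and 0.518%, and tumour or epithelial-like cells 9.78% and 5.94%. No cluster was named mast, type 2 innate lymphoid, endothelial or erythroid-like.

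Within T-like cells (1329 WT, 2291 KO) the CD8 T-like share was 30.7% (28.2 to 33.3) in WT and 18.9% (17.3 to 20.5) in KO. The regulatory T-like share was 14.7% (12.8 to 16.7) against 9.08% (7.93 to 10.3), and conventional CD4 T-like cells were 11.1% (9.49 to 12.95) against 15.8% (14.4 to 17.4). Gamma-delta T-like cells were 9.93% (8.38 to 11.7), 132 cells, in WT and 0.436% (0.210 to 0.801), 10 cells, in KO, log2 -4.51 (-1.43 with the marker score per cell). T cluster 7, whose cells carry Lef1 and Ccr7 of resting lymph-node T cells, held 2.11% of WT and 38.7% of KO T-like cells. Unnamed subclusters held 33.6% of WT and 55.8% of KO T-like cells, so these shares depend on which cells could be named. The large cluster 7 also lowers the other shares of KO T-like cells. Of all kept cells, CD8 T-like cells were 4.23% in WT and 3.80% in KO, log2 -0.15 (-0.35 to 0.037). Regulatory T-like cells were 2.02% and 1.83%, log2 -0.14 (-0.42 to 0.14). Conventional CD4 T-like cells were 1.54% and 3.20%, log2 1.06 (0.78 to 1.33), and gamma-delta T-like cells 1.37% and 0.0880%.

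**Figure D2:**
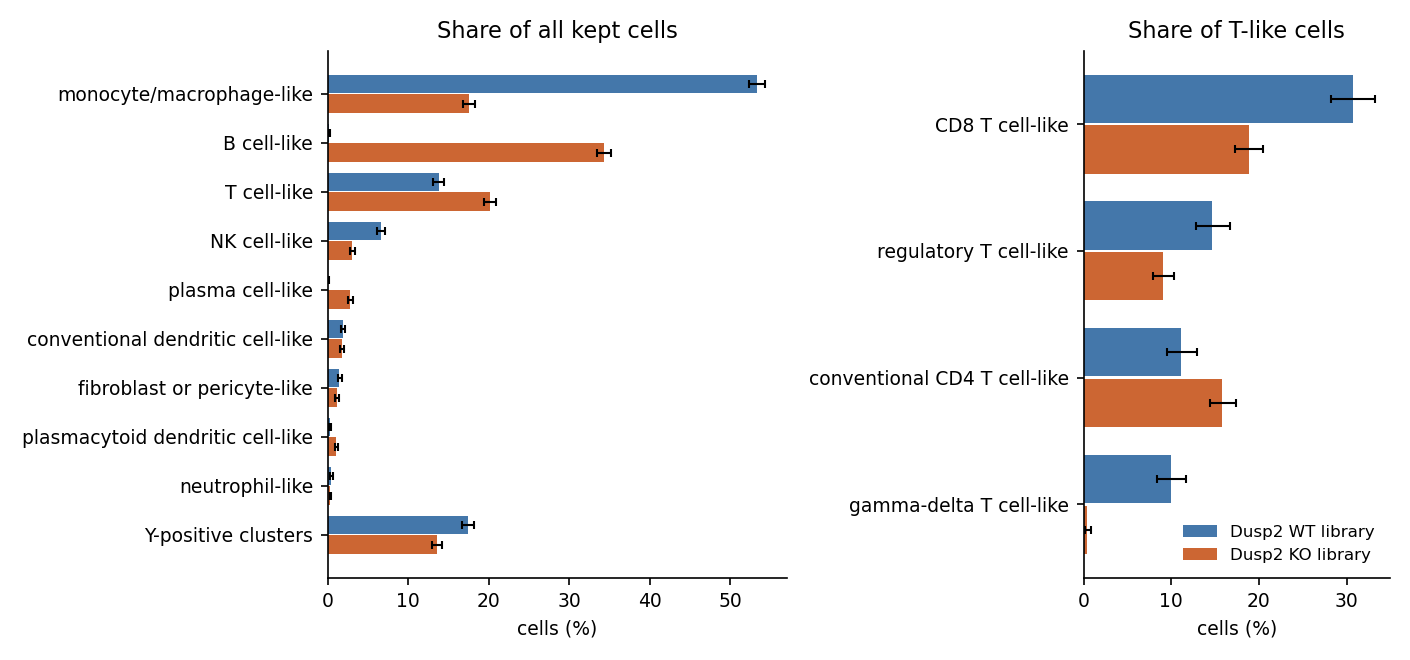
Share (percent) of all kept cells in each cell class, left, and of T-like cells in each T class, right, in the WT and KO libraries, 1 library each. Bars are 95% Clopper-Pearson intervals that cover counting error only.

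CD8 T-like cells of the KO library had lower inhibitory-receptor RNA, more granzyme A and B, and less granzyme D and E. Pdcd1, the gene for PD-1, was 591 (561 to 621) in WT and 216 CPM (197 to 237) in KO, log2 -1.45 (-1.60 to -1.30). Of 16 measured inhibitory receptor and exhaustion genes, 2 were higher and 14 lower, with a median of -1.19, half-width 0.27, and percentile 0. Markers of some other cell types were lower in the same cells too. Medians were -0.88 for monocyte/macrophage (18 of 24 lower), -0.81 for neutrophil (7 of 9) and -0.68 for NK markers (6 of 9). B-cell and plasma-cell markers were higher, at 3.05 (9 of 9 higher) and 5.01 (6 of 7). Tox, a transcription factor of exhausted T cells, was at -2.09 (-2.34 to -1.84), and the receptor genes Cd244a and Cd200r1 at -2.16 and -2.13. Cd101 was higher, 1.15 (0.79 to 1.53), and Havcr2, the gene for TIM-3, was level at 0.12 (-0.17 to 0.40). Gzmb, a granule protease of killer cells, was 914 (878 to 952) against 2029 CPM (1970 to 2090), log2 1.15 (1.08 to 1.22).

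The 12 named genes higher in KO CD8 T-like cells began with Ifitm1, an interferon-induced membrane protein, 417 (392 to 443) against 3416 CPM (3338 to 3495), log2 3.04 (2.94 to 3.13). Gzma, another granule protease, was at 2.86 (2.72 to 3.01), 179 against 1301 CPM. Itgae and Itgb7, the 2 chains of the epithelial-homing integrin CD103/beta 7, were at 2.60 (2.16 to 3.07) and 1.38 (1.16 to 1.59). St8sia1, a ganglioside synthase, followed at 2.30 (1.93 to 2.68), Ifitm2 at 1.66, Arl4c at 1.47, Ly6a (Sca-1) at 1.33, Rrm2, which makes deoxynucleotides, at 1.53, Cd7 at 1.60 (-0.079 with the marker score per cell), Gpr55 at 1.72 and Ly6a2 at 1.70. Ly6a2 and Ly6a are close paralogs that 3' reads may not separate.

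Next to Dusp2 among the lower genes was Klrh1, an NK-type lectin receptor, with 227 UMIs in WT and 1 in KO, log2 -7.59 (-12.9 to -5.09). Serpinb9b, a granzyme-inhibitor relative, had 173 and 1, -7.19 (-12.5 to -4.70). Then came Gldc, a glycine-cleaving enzyme, -4.11 (-5.14 to -3.25), Creb3l2 -3.27, Gzme -3.54, Itga4, the alpha 4 integrin of VLA-4, -3.23 (-3.75 to -2.75), Gzmd -3.52, Serpine2 -3.52, Ier5l -2.97, Setbp1 -2.54 and Bend4 -2.66. Gzmd and Gzme are near-identical relatives, so their separate levels are uncertain. CD8 subclusters 1, 8, 10, 16 and 17 held 54.4%, 35.0%, 2.21%, 1.72% and 6.62% of the WT cells and 46.8%, 8.80%, 29.2%, 13.7% and 1.62% of the KO cells, so the class is not the same mix in both libraries. Within subcluster 1 alone the inhibitory receptor and exhaustion median was -0.74. There Klrh1 had 10 WT and 0 KO UMIs, at least 3.66-fold lower, and Serpinb9b and Serpine2 each 2 and 1, log2 -1.13 (-7.01 to 3.13), too few for a direction. Gldc had 13 and 6 UMIs, log2 -1.25 (-2.93 to 0.25), and Gzme 21 and 1, log2 -4.53 (-9.89 to -1.89), with 15 of the 21 in 1 cell. Creb3l2 was at -1.83 (-2.74 to -1.002) and Itga4 at -3.02 (-3.87 to -2.26). The named higher genes spanned 0.67 for Itgb7 to 2.14 for Ifitm1, with Rrm2 at 1.33 (-0.43 to 3.43) from 4 and 11 UMIs, also too few for a direction.

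**Figure D3:**
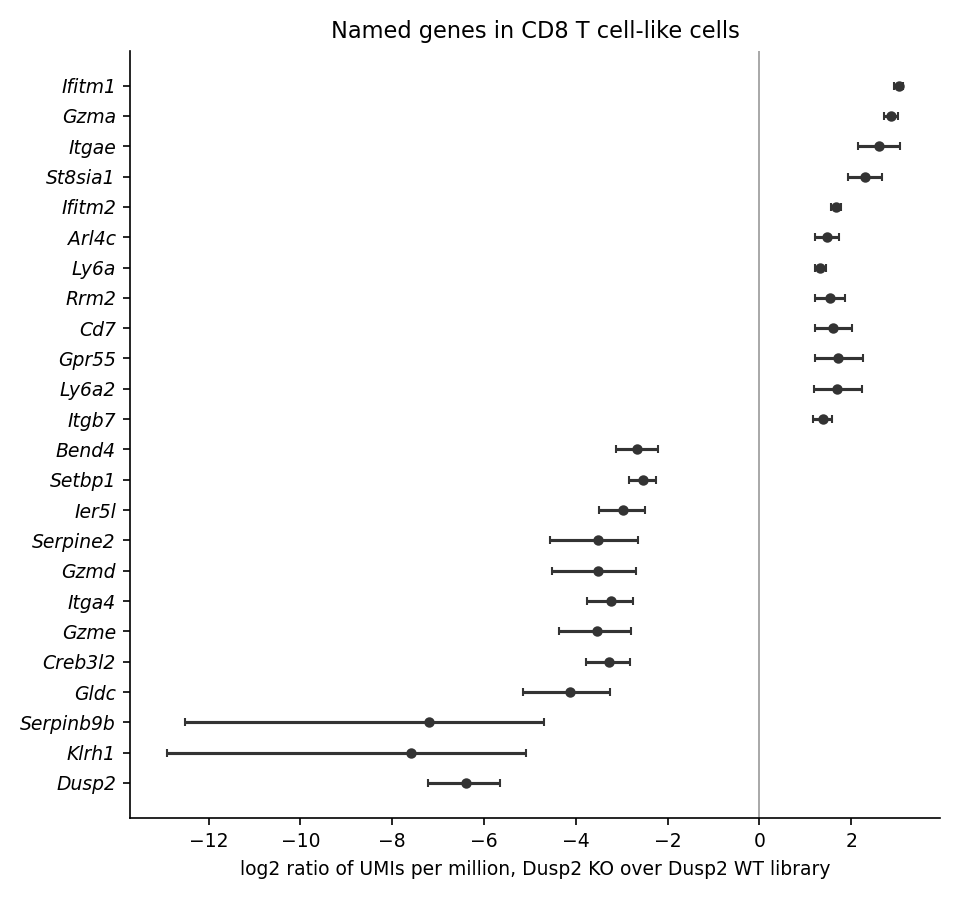
Log2 ratio of CPM, KO over WT library, of the 12 named genes per direction in CD8 T-like cells, 1 library per genotype. Bars are 95% intervals that cover counting error only.

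Type I interferon response genes in CD8 T-like cells had a median of 0.25, half-width 0.15, percentile 100, with 25 of 40 higher and 15 lower. Ly6a and Isg20, an RNA exonuclease at 0.997 (0.63 to 1.37), were highest, and Ddx60 and Usp18, a brake on interferon signalling, were lower at -1.55 (-2.57 to -0.64) and -1.18. Isg15, a ubiquitin-like response gene, was level at 0.046 (-0.22 to 0.32). The list median was -0.13 with the stricter cell filter, -0.0089 with cells thinned before clustering and -0.17 within subcluster 1. Interferon receptor and ligand genes had a median of 0.062, percentile 74.5, 6 of 10 higher and 4 lower, with Socs1 at 1.07 and the receptor gene Ifnar1 at -0.44 (-0.68 to -0.19). NFAT-linked genes split, median -0.059, percentile 41.6, with 8 of 18 higher and 10 lower. Cd40lg (1.78) and Tnf (1.40) were higher, and Tox and Nr4a2 (-1.86) lower. Nfatc1 itself was 136 (122 to 151) against 68.9 CPM (58.2 to 80.9), log2 -0.98 (-1.27 to -0.70). ERK and immediate-early genes, a readout of the kinases Dusp2 acts on, had a median of -0.30, percentile 0.745, 8 of 25 higher and 17 lower, with Fosl2 at -2.10 (-2.47 to -1.75), Spred1 at -0.97 and Ier5 at 0.50. Other dual-specificity phosphatases had a median of -0.43, percentile 1.35, 5 of 14 higher and 9 lower, with Dusp16 at -1.55 and Dusp3 at -1.11, and the median was 0.036 within subcluster 1.

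Cell-cycle genes were higher in KO CD8 T-like cells, 30 of 32 measured, median 0.64, half-width 0.10, percentile 100. Rrm2 and the mitotic kinase Bub1 (1.10) led, and Cenpa (-1.17) and Ube2c (-0.40) were the 2 lower. Stmn1, a member of this list, was among the leading genes of subclusters 16 (7 WT, 59 KO cells) and 17 (27 and 7). Within subcluster 1 the median was 0.42, half-width 0.29, with 13 of 17 higher. Naive and memory genes had a median of 0.51, percentile 100, 12 of 17 higher and 5 lower, with Il7r, the interleukin 7 receptor, at 1.32 (1.16 to 1.47), Id3 at 1.46 and Tcf7 at 0.77 (0.40 to 1.13). Bach2 and Dapl1 ran the other way, -1.19 (-1.32 to -1.06) and -1.84. Within subcluster 1 the naive and memory median was -0.00082, percentile 71.4, with 8 of 16 higher and 8 lower. Cytotoxic effector genes had a median of -0.054, percentile 16.3, 9 of 24 higher and 15 lower. The effector cytokine Ifng was 177 against 205 CPM, log2 0.21 (0.018 to 0.40), and -0.15 with the stricter cell filter. Co-stimulatory receptors had a median of -0.46, percentile 0.8, 2 of 10 higher and 8 lower, with Cd27 at -1.02 (-1.23 to -0.81) and Cd2 at 0.60.

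MHC class I presentation had a median of 0.25, percentile 99.5, 12 of 16 higher and 4 lower, with the proteasome activator Psme2 at 0.64 and Tap2 at 0.37. MHC class II had a median of 0.28, percentile 98.0, 7 of 11 higher and 4 lower, led by the B-cell gene H2-Ob, 0 against 22 UMIs, at least 8.66-fold. The median was -1.16 with the marker score per cell and -0.089 with every barcode, and B-cell markers were at 3.05 (9 of 9 higher) in the same cells. Regulatory T genes had a median of 0.048, percentile 73.4, 10 of 19 higher and 9 lower, with Ikzf2 at -1.48 and Tnfrsf4 at -1.47. Glycolysis and hypoxia genes had a median of 0.066, percentile 80.0, 14 of 23 higher and 9 lower, with Eno1 at 0.43 and Hilpda at -1.13. Oxidative phosphorylation had a median of 0.084, percentile 89.6, 36 of 43 higher and 7 lower, with Uqcr10 at 0.39. Heat shock and dissociation genes had a median of -0.069, percentile 34.2, 7 of 16 higher and 9 lower, with Hspa8 at 0.35 and Bag3 at -1.12.

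Macrophage, neutrophil and suppressive-enzyme lists were also measured in CD8 T-like cells, and which cells this RNA came from was not tested. Alternatively activated macrophage genes had a median of -0.99, percentile 0, 4 of 15 higher and 11 lower, with the platelet-factor gene Pf4 at -3.33. Inflammatory macrophage genes had a median of -0.13, percentile 26.4, 9 of 19 higher and 10 lower, with Il1b at -1.87. Checkpoint ligands and suppressive enzymes had a median of -0.097, percentile 46.5, 5 of 14 higher and 9 lower, with Cd47 at 0.55. Myeloid transcripts had a median of -0.43, percentile 1.34, 5 of 11 higher and 6 lower, and neutrophil transcripts -0.72, percentile 0.610, 1 of 4 higher and 3 lower. Haemoglobin had too few UMIs for a value. Lyz2, a macrophage gene, was 154 CPM in WT and 82.9 in KO CD8 T-like cells, and the antibody gene Igkc 3.55 and 708 CPM. Thinned to 2000 UMIs, 0.775% of WT and 75.1% of KO CD8 T-like cells carried Igkc, and Igkc was found in every class of the KO library.

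Monocyte/macrophage-like cells (5143 WT, 1994 KO) of the KO library had more Cxcl9, a chemokine that draws T cells, 682 (674 to 689) against 1180 CPM (1163 to 1198), log2 0.79 (0.76 to 0.82). Nos2, the inducible nitric oxide synthase, was at 1.17 (1.01 to 1.33), Mmp12, an elastase, at 0.98 (0.91 to 1.06) and Gpnmb at 0.94 (0.83 to 1.049). The acute-phase gene Saa3 was at 2.59 (2.45 to 2.73), with 347 of 1218 KO UMIs in 1 cell. Other named genes were Ly6i at 1.35 (1.25 to 1.44), Ass1, which remakes arginine, at 0.92, Upp1 at 0.73, Slc13a3 at 0.80, Inhba at 0.69 and Calhm6 at 0.72. Junos, at 1.08, lies opposite Jun, and the strand setting of the counting is not given in the sources used here.

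Lower in KO were Chil3, a chitinase-like gene of alternatively activated cells, 133 (129 to 136) against 35.8 CPM (32.8 to 39.0), log2 -1.89 (-2.02 to -1.76), and Mgl2, the lectin CD301b, -1.30 (-1.40 to -1.20). Cdk8, a Mediator kinase, was at -1.49 (-1.52 to -1.45), Ccl24, an eosinophil chemokine, at -1.21, Vcan, a matrix proteoglycan of monocytes, at -1.10 (-1.16 to -1.04), and Il1r2, a decoy receptor for interleukin 1, at -1.12. Lyz1 (-1.18), Cbfa2t3 (-1.19), Tmtc2 (-1.09) and Trerf1 (-1.13) were also lower. Lyz1 has a close paralog in Lyz2, so its level is uncertain. Clusters 1, 2, 3 and 8 held 25.5%, 22.4%, 23.7% and 13.6% of WT and 24.8%, 32.05%, 20.2% and 8.63% of KO cells of this class.

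All 12 MHC class II presentation genes were higher in KO macrophage-like cells, median 0.26, half-width 0.017, percentile 99.9. Cd74, the invariant chain, was at 0.39 (0.38 to 0.40), and H2-Oa (2.36) and H2-Ob (1.74), genes of B cells, showed the largest ratios. B-cell markers, whose cells also carry MHC class II, had a median of 4.35 (20 of 20 higher) in the same cells, plasma-cell markers 8.34 (10 of 10) and T-cell markers 1.33 (23 of 26). By cluster the median was 0.56 in cluster 1, 0.21 in cluster 2 and 0.45 in cluster 8, but -0.096 in cluster 3, with 4 genes higher and 8 lower. MHC class I genes had a median of 0.20, percentile 100, 14 of 16 higher and 2 lower, with Psme2 at 0.55 (0.52 to 0.59) and H2-Q4 at 0.42. Alternatively activated and tissue-remodelling genes had a median of -0.15, percentile 0.685, 11 of 31 higher and 20 lower, with the hyaluronan receptor Lyve1 at -2.55 (-3.32 to -1.86) beside Chil3. By cluster it was -0.20, -0.15 and -0.044 in clusters 1, 2 and 3 and 0.11, percentile 99.1, in cluster 8. Inflammatory macrophage genes had a median of -0.036, percentile 51.2, 12 of 27 higher and 15 lower, with Nos2 and Cxcl9 against Il12b at -1.25 (-3.62 to 0.48) and Ptgs2 at -0.40. Clusters differed here too, with 0.15, percentile 99.96 and 20 of 26 higher in cluster 2, against -0.091, -0.0018 and -0.11 in clusters 1, 3 and 8. Checkpoint ligands and suppressive enzymes had a median of -0.091, percentile 36.8, 6 of 19 higher and 13 lower, with Cd274 (PD-L1) at 0.17 (0.11 to 0.22), the suppressive cytokine Il10 at -0.71 (-0.81 to -0.61) and Vsig4 at 28 against 0 UMIs, at least 2.89-fold lower.

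Type I interferon response genes had a median of -0.18 in macrophage-like cells, half-width 0.054, percentile 0.120, 15 of 45 higher and 30 lower. Clusters did not agree, with -0.15 in cluster 3 (percentile 1.97), -0.071 in cluster 1 (44.5), 0.0070 in cluster 2 (81.6) and 0.14 in cluster 8 (99.9, 29 of 45 higher). With the marker score per cell the median was 0.0042. The antiviral Oas2 was at -0.62 (-0.90 to -0.35) and Ifit1bl1 at -0.93, while Ifi47 (0.54) and Ly6a (0.51) were higher. Interferon receptor and ligand genes had a median of -0.22, percentile 3.14, 3 of 11 higher and 8 lower, with Ifnb1, the interferon-beta gene, at -0.59 (-1.03 to -0.18). NFAT-linked genes had a median of -0.31, half-width 0.15, percentile 0.0900, 6 of 21 higher and 15 lower, with Nfatc2 at -0.73 (-0.91 to -0.54) and Nr4a3 at -0.63, and the median was -0.013 with doublets kept. ERK and immediate-early genes had a median of 0.026, percentile 85.8, 14 of 27 higher and 13 lower, with Myc at 0.67 and Fosb at -0.65. Other dual-specificity phosphatases had a median of 0.029, percentile 80.6, 10 of 18 higher and 8 lower, with Dusp6 at 0.64.

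Glycolysis and hypoxia genes had a median of 0.14, percentile 99.99, 15 of 26 higher and 11 lower, with the glucose transporter Slc2a1 at 0.46 (0.39 to 0.53). Oxidative phosphorylation had a median of 0.031, percentile 98.9, 30 of 43 higher and 13 lower, with Sdhd at 0.30. Cell-cycle genes had a median of -0.10, percentile 10.8, 12 of 32 higher and 20 lower, with Mki67 at -0.46. Heat shock and dissociation genes had a median of -0.0098, percentile 67.4, 6 of 16 higher and 10 lower, with Hspa1b at -0.76. Neutrophil transcripts had a median of 0.080, percentile 65.3, 5 of 7 higher and 2 lower, myeloid transcripts 0.022, percentile 47.6, 8 of 11 higher and 3 lower, and haemoglobin -1.39, all 3 lower.

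Lymphocyte lists were also measured in macrophage-like cells, and which cells this RNA came from was not tested. Co-stimulatory receptors had a median of 0.67, percentile 100, 8 of 10 higher and 2 lower, with Cd28 at 1.67 and Icos at 1.49 against Cd226 at -1.43. Naive and memory genes had a median of 0.25, percentile 100, 10 of 16 higher and 6 lower, with Satb1 at 2.71 and Tcf7 at 2.66. Cytotoxic effector genes had a median of 0.082, percentile 86.4, 14 of 22 higher and 8 lower, regulatory T genes 0.057, percentile 88.0, 11 of 18 higher and 7 lower, and inhibitory receptor and exhaustion genes -0.092, percentile 40.1, 6 of 15 higher and 9 lower. Igkc was 0.886 CPM in WT and 1026 in KO macrophage-like cells.

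**Figure D4:**
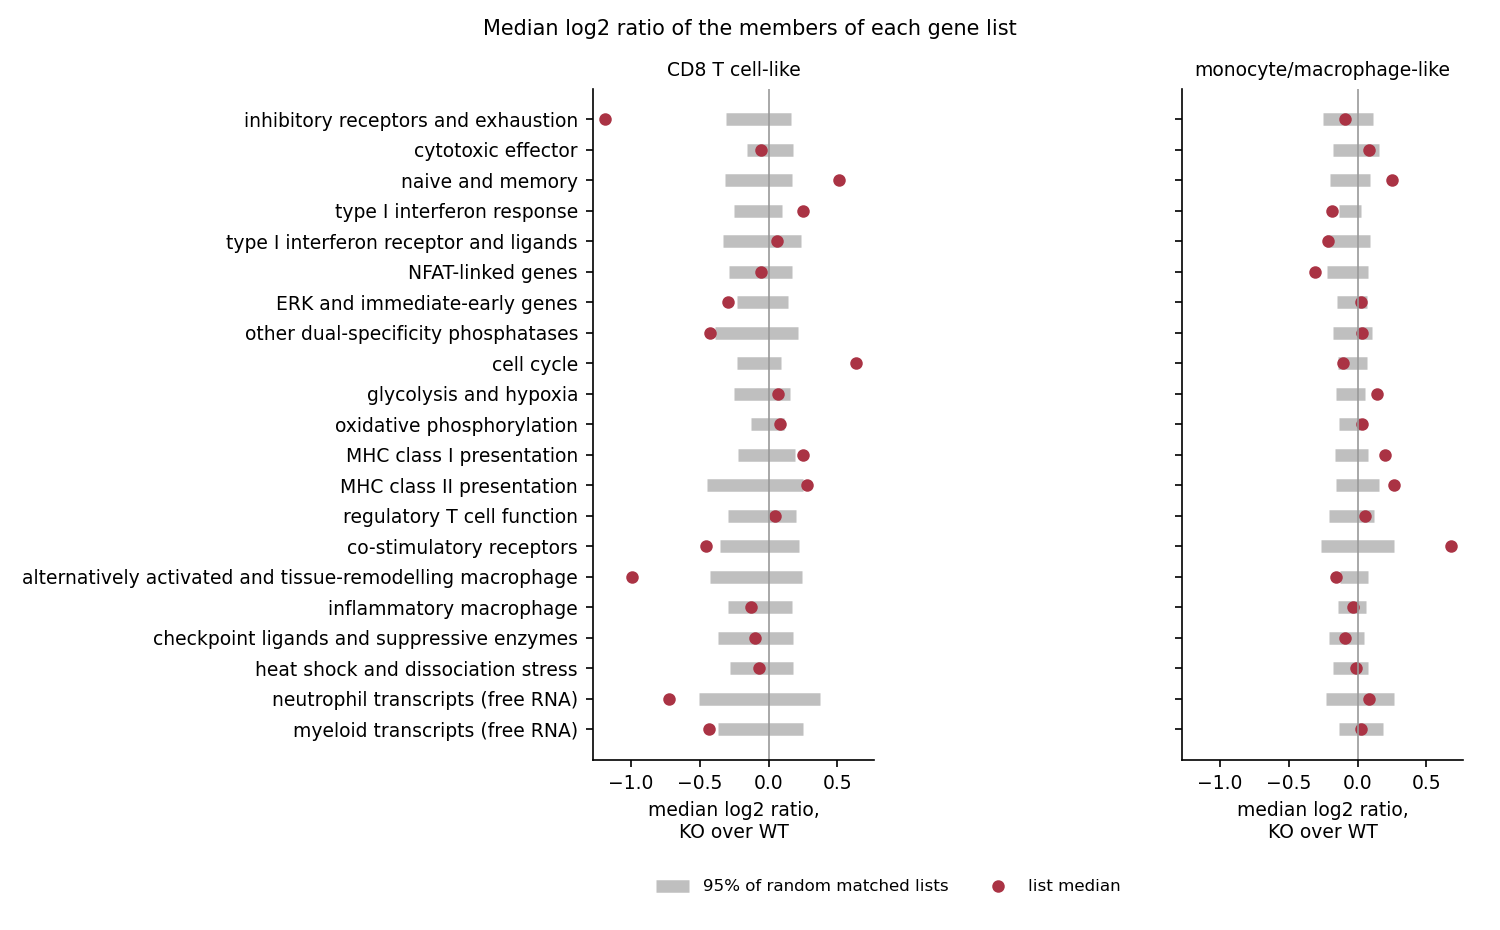
Median log2 ratio, KO over WT library, of each gene list but haemoglobin (points) in CD8 T-like cells, left, and monocyte/macrophage-like cells, right, 1 library per genotype. Grey bars hold 95% of the medians of random lists of matched level.

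Conventional CD4 T-like cells (148 WT, 363 KO) of the KO library carried Tox2 and Il21, genes of T cells that help B cells. Tox2 had 1 WT and 138 KO UMIs, log2 5.82 (3.32 to 11.1), and Il21 1 and 38, 3.96 (1.40 to 9.30). Within subcluster 4 Tox2 had 1 and 3 UMIs, log2 1.44 (-2.20 to 7.15), too few for a direction. Fbn2 had 0 and 205 UMIs, at least 28.0-fold. The B-cell genes Cd79a, 0 and 107 UMIs, at least 14.6-fold, and Ebf1, 1 and 111 UMIs, 5.51 (3.001 to 10.8), were also among the highest. Interferon response genes were lower, 40 of 42, median -1.32, percentile 0, with Rsad2, an antiviral enzyme, at -3.35 (-4.00 to -2.74). Oasl1 was at -6.73 (-9.80 to -4.83) with 42 of 87 WT UMIs in 1 cell, Ccl4 at -5.35 with 112 of 201 in 1 cell, and Palld at -5.21. NFAT-linked genes had a median of -0.26, percentile 2.32, 6 of 18 higher and 12 lower, with the cytokine genes Csf2 and Lif at -3.57 and -2.87. Naive and memory genes had a median of 0.59, percentile 100, 12 of 17 higher and 5 lower, with Dapl1 at least 7.93-fold higher and Il7r at -0.95, and the median was -0.040 within subcluster 4. Subcluster 4 held 87.2% of the WT cells and 38.8% of the KO cells, and subcluster 7 held 2.03% and 58.7%. The interferon response median was -0.60 within subcluster 4 and 0.011 with the stricter cell filter, where Oasl1 was at 0.27 and Ccl4 at 1.08. Markers of some other cell types were lower in the same cells too. Medians were -1.24 for monocyte/macrophage (19 of 20 lower), -1.44 for neutrophil (8 of 10) and -1.37 for type 2 innate lymphoid markers (9 of 10). B-cell and plasma-cell markers were higher, at 2.45 (11 of 11 higher) and 3.32 (6 of 6).

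Regulatory T-like cells (195 WT, 208 KO) had lower interferon response RNA, 29 of 32 genes, median -0.61, half-width 0.18, percentile 0, with Ddx60 at -1.87 and Samd9l at -1.54 (-2.03 to -1.06). Monocyte/macrophage and neutrophil markers were lower in the same cells as well, medians -0.76 (16 of 19 lower) and -0.61 (8 of 9). B-cell and plasma-cell markers were higher, medians 2.83 (9 of 10 higher) and 6.2 (8 of 8). Regulatory function genes had a median of -0.42, percentile 0.420, 5 of 21 higher and 16 lower, with the ectoenzyme Entpd1 (CD39) at -1.20 (-1.53 to -0.87) and Klrg1 at -1.03. NFAT-linked genes had a median of -0.27, percentile 17.2, 8 of 17 higher and 9 lower. Aff3 (2.52) and Tbc1d4 (2.45), a glucose-uptake regulator, were higher, and Frmd5 (-3.19), the chemokine gene Ccl5 (-2.36) and Cep112 (-2.84) lower. Slpi at 7.39 and Mzb1 at least 87.5-fold rest on 1 cell each, with 1390 of 1433 and 307 of 320 KO UMIs, and Tbc1d4 was at 0.98 with the marker score per cell. Subclusters 3 and 13 held 82.1% and 17.9% of WT and 74.0% and 26.0% of KO cells. The regulatory function median was 0.14 with cells thinned before clustering.

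NK-like cells (640 WT, 343 KO) had more granzyme F and G, Gzmf 74.9 against 3121 CPM, log2 5.38 (5.20 to 5.56), and Gzmg 5.81 (5.31 to 6.36). Only 35 of 343 KO cells, 10.2%, held Gzmf UMIs and 20, 5.83%, Gzmg, against 6 and 8 of 640 WT cells. Of 5420 KO UMIs of Gzmf, 1339 lie in 1 cell, and the 2 genes are close paralogs. Spp1, osteopontin, was at 2.63 (2.51 to 2.74), and Slpi at 5.01 with 451 of 507 UMIs in 1 cell. Beside Dusp2, the named lower genes were Cdk8 (-1.69), Ccl6 (-1.84, but -0.011 with the marker score per cell) and Tmem254 (-1.63). Cytotoxic effector genes had a median of 0.20, percentile 99.9, 14 of 23 higher and 9 lower. Interferon response genes were higher here, median 0.30, percentile 99.99, 24 of 33 higher and 9 lower, with Ly6a at 2.05 (1.80 to 2.30), Ifit1 at 1.83 (0.48 to 3.29) with 9 of 14 KO UMIs in 1 cell, and Oasl2 at -2.44 (-5.57 to -0.41), but the median was 0.038 with the marker score per cell. Markers of other cells differed in the same cells. Medians were 0.86 for conventional dendritic (7 of 9 higher), 0.76 for tumour or epithelial (8 of 8 higher) and -0.88 for monocyte/macrophage markers (19 of 26 lower). The largest were 4.43 for B-cell (6 of 6 higher) and 5.83 for plasma-cell markers (9 of 9). NFAT-linked genes had a median of -0.27, percentile 6.98, 5 of 16 higher and 11 lower, with Nfatc2 at -1.004 and Nfatc1 at -0.86 (-1.04 to -0.69).

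Conventional dendritic-like cells (179 WT, 200 KO) had all 12 MHC class II genes higher, median 0.44, percentile 99.99, but 0.067 with the marker score per cell. The class is cluster 16, with Ccr7 and Fscn1 among its leading genes, and leaves out unnamed cluster 11 (414 WT, 351 KO). B-cell markers, whose cells also carry MHC class II, had a median of 3.77 (10 of 10 higher) in the same cells. Monocyte/macrophage markers were at -0.93 (19 of 26 lower) and the class's own markers at -0.37 (14 of 25 lower). Gpr15lg, a chemoattractant gene, was at 6.22 (4.34 to 9.29), the epithelial transcription factor gene Ehf at 4.89 and Asprv1 at 5.42 (3.52 to 8.50). Ebf1, a B-cell gene, had 0 against 127 UMIs, at least 49.1-fold, with 50 UMIs in 1 cell. Thbs1 (-3.15, but -0.74 with arithmetic folds for naming), Pf4 (-3.35) and the phosphodiesterase gene Pde4d (-1.95) were lower. Interferon response genes had a median of -0.14, percentile 30.2, 8 of 26 higher and 18 lower, and NFAT-linked genes -0.13, percentile 30.4, 5 of 11 higher and 6 lower.

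Fibroblast-like cells (141 WT, 130 KO) had more Brinp3, 4.14 (3.70 to 4.60), and Col7a1, an anchoring collagen, 4.34 (3.53 to 5.27). Cd79a was at 4.72, and H2ac24 at 5.51 (3.60 to 8.58) with 59 of 69 UMIs in 1 cell. Lower were the basement-membrane gene Ntn4 (-5.01, interval -8.08 to -3.11), Plac9 (-3.09), the chemokine gene Cxcl14 (-3.38) and the muscle actin gene Acta2 (-3.78). Dusp2 was lower too, 24.6 (17.1 to 34.4) against 5.73 CPM (2.10 to 12.5), log2 -2.10. Of its 34 WT UMIs, 13 lay in 1 cell, and KO held 6 UMIs. Interferon response genes had a median of -0.41, percentile 0, 7 of 36 higher and 29 lower, with Ifit3b at -3.41 (-6.52 to -1.42) and Ifit3 at -2.20, and NFAT-linked genes -0.28, percentile 4.42, 6 of 15 higher and 9 lower. Markers of other cells differed in the same cells, with medians of 7.38 for erythroid (65 and 1827 UMIs, 4 of 5 higher), 3.29 for B-cell (5 of 6 higher) and -0.60 for endothelial markers (4 of 6 lower).

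Y-positive cells (1681 WT, 1546 KO) had all 32 cell-cycle genes higher in KO, median 0.39, percentile 100. Their mix differed, with 825 WT and 385 KO cells in cluster 4, 391 and 571 in cluster 6 and 315 and 545 in cluster 9. Fibroblast markers had a median of -0.78 (17 of 18 lower) and monocyte/macrophage markers -1.16 (29 of 33 lower). B-cell markers were at 4.55 (19 of 19 higher), plasma-cell markers at 5.04 (9 of 10) and T-cell markers at 1.01 (20 of 24). The protease inhibitor Slpi was at 2.42 (2.35 to 2.49), Cxcl9 at 1.38, the histone gene H4c4 at 1.19 and Csf3, the neutrophil growth factor, at 1.16. Slpi is also among the leading genes of plasma-like cluster 19, with 4 WT and 318 KO cells. The matrix genes Lum (-3.18) and Dcn (-1.88), Ccl6 (-1.60) and Dlg2 (-1.39) were lower. MHC class I genes had a median of 0.20, percentile 99.9, 14 of 16 higher and 2 lower. Interferon response genes had a median of 0.064, percentile 98.8, 28 of 44 higher and 16 lower, and NFAT-linked genes -0.14, percentile 26.9, 7 of 21 higher and 14 lower.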

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

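Values are log2 KO over WT. The B-like share kept its direction in all 10 alternatives (7.68 to 8.43), the exhaustion median in CD8 T-like cells in all 16 (-1.36 to -0.74), the interferon response median in regulatory T-like cells in all 15 (-0.81 to -0.45), and the CD8 cell-cycle median in all 16 (0.41 to 0.84). Over all classes and lists, including those not reported, 170 list medians met 2542 alternatives, and 232 of these had another sign, spread over 90 medians. The median KO cell holds fewer UMIs, but intervals for levels depend on the summed UMIs of the class. For genes of low level the library with the smaller sum has the wider interval. This is KO in CD8 T-like (2148018 against 2536305 UMIs in WT), macrophage-like, NK-like, conventional dendritic-like and fibroblast-like cells and Y-positive clusters. It is WT in conventional CD4 T-like (681555 against 1661930 in KO) and regulatory T-like cells (1282838 against 1563920). Some settings give no value: the marker score for fibroblast-like cells, Y-positive clusters and haemoglobin, resolution 2 and thinning for the gamma-delta T-like share, and members of at least 100 UMIs for haemoglobin. No paired analysis was possible because each genotype is 1 library. Where a value below moved or turned, the cause was not tested.

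With the stricter cell filter the CD8 exhaustion median was -0.88, the CD8 interferon response median -0.13, the conventional CD4 interferon response median 0.011, Oasl1 there 0.27, Ccl4 there 1.08, and Ifng in CD8 T-like cells -0.15. With every barcode the plasma-like share was 8.09 and MHC class II in CD8 T-like cells -0.089.

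With doublets kept the macrophage-like share was -1.50, the regulatory T-like share -1.01, NFAT-linked genes in CD8 T-like cells -0.24 and in fibroblast-like cells 0.12, and Ifng in CD8 T-like cells -0.11. In macrophage-like cells cell cycle was 0.053 and myeloid transcripts -0.041. With the expected doublet rate in both libraries, added later, the macrophage-like share was -1.54, conventional CD4 T-like 0.17, fibroblast-like 0.14, myeloid transcripts in macrophage-like cells -0.0020 and NFAT-linked genes in fibroblast-like cells 0.085.

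With resolution 0.5 the plasma-like share was 4.07, the conventional CD4 T-like share 0.84 and the CD8 exhaustion median -0.81. With resolution 2 the T-like share was 0.69, the conventional CD4 T-like share 0.93 and NFAT-linked genes in conventional CD4 T-like cells 0.038. With the marker score per cell the macrophage-like share was -1.86, conventional dendritic-like -0.61 and conventional CD4 T-like 0.96. In CD8 T-like cells the interferon response was 0.021, MHC class II -1.16, Cd7 -0.079 and Ifng -0.11. The interferon response in macrophage-like cells was 0.0042, Ccl4 in conventional CD4 T-like cells 2.34 and Slpi in regulatory T-like cells -1.34.

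With cells thinned before clustering the NK-like share was -1.34, plasma-like 8.11 and regulatory T-like -0.96. The CD8 exhaustion median was -0.75, the CD8 interferon response -0.0089, and alternatively activated genes in macrophage-like cells -0.22. In regulatory T-like cells NFAT-linked genes were 0.072, regulatory function 0.14 and Slpi -1.63. With clustering without list genes, added later for shares, the CD8 T-like share was -1.07, regulatory T-like -0.96 and conventional CD4 T-like 0.19. The CD8 exhaustion median was -0.87, the CD8 interferon response 0.040 and regulatory function in regulatory T-like cells 0.037.

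Without B-like and plasma-like cells in the denominator, added later, the T-like share was 1.22, NK-like -0.47, macrophage-like -0.94, conventional dendritic-like 0.59 and fibroblast-like 0.31, which follows from the smaller denominator. With the mean of each cell's CPM Dusp2 was -3.93 over all cells and -6.21 outside the Y-positive clusters. In CD8 T-like cells the interferon response was 0.0055, neutrophil transcripts 0.11 and Ifng -0.073. Alternatively activated genes in macrophage-like cells were -0.28 and NFAT-linked genes in fibroblast-like cells 0.058. With members of at least 5 UMIs, NFAT-linked genes in regulatory T-like cells were 0.0096. In CD8 subcluster 1 alone, added later, exhaustion was -0.74, interferon response -0.17, naive and memory -0.00082 and other dual-specificity phosphatases 0.036. In conventional CD4 subcluster 4 alone, added later, naive and memory was -0.040.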

Other observations

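B-like cells of the KO library include a group with germinal-centre genes. Clusters 12 and 18 hold 1071 of the 3904 KO B-like cells, 27.4% (26.0 to 28.9), and 0 WT cells. Rgs13, a signalling regulator of these cells, was 133 CPM (125 to 140) there and 5.03 (3.81 to 6.52) in B-like clusters 0 and 23 of the same library. S1pr2, a receptor that keeps cells in the follicle centre, was 67.9 against 1.59 CPM, and the proliferation gene Mki67 414 against 10.8. Ighd, of resting B cells, ran the other way, 17.9 against 476. Plasma-like KO cells held mostly switched heavy chains, with Ighg2b 53.8%, Ighg1 26.8%, Ighg2c 14.4%, Ighg3 2.29%, Ighm 1.57% and Igha 0.942% of heavy-chain UMIs. Ighg2b and Ighg2c are close paralogs. These genes were looked up after the clusters were seen, and the clustering used genes like them, so the values describe the clusters.

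Cluster 32 holds 2 WT and 22 KO cells with genes of lymphoid stroma. In KO it carried Cxcl13, which draws B cells, at 6539 CPM (6207 to 6884), Ccl21a at 1891 CPM with 217 of 420 UMIs in 1 cell, the complement receptor gene Cr2 at 297 (230 to 378) and the vessel address gene Madcam1 at 162 (114 to 224). T subcluster 7, with 213 of the 363 KO conventional CD4 T-like cells, carried Cxcr5 at 95.4 CPM (76.9 to 117), Bcl6 at 95.4 and Il21 at 38.4 (27.0 to 52.9), genes of T follicular helper cells. Igkc was found across KO classes, 720 CPM in conventional dendritic-like and 611 in fibroblast-like cells against 0 and 0.724 in WT. In NK-like cells it was 7650 CPM, with 11434 of 13284 UMIs in 1 cell.

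B-like, plasma-like and resting T-like cells lay almost only in the KO library. The tests on Dusp2, on T cluster 7 and on T and NK markers were chosen after the result was seen, and the test on Lyz2 before. Cells of an animal with intact Dusp2 are argued against by Dusp2 at 0.886 CPM (upper bound 1.40) in KO B-like cells, against 744 (552 to 981) in WT, from 50 UMIs of 14 cells with 15 in 1 cell. Lyz2 was at 67.8 CPM (upper bound 71.4) in KO B-like cells, against 10230 in KO macrophage-like cells. T markers there were at a median of 0.608% (upper bound 0.721) of their level in T-like cells, and NK markers at 0.103% (0.138) of that in NK-like cells. So the B-like cells held little RNA of those classes. Clusters were formed on variable genes that could include these markers and named by the highest marker score, so low values are partly built in. They do not decide whether doublets or free RNA gave B-cell RNA to macrophage-like, T-like or NK-like cells. A lymph node taken with the tumour and a lymphoid structure within it both predict resting T cells, so the 38.7% of KO T-like cells in cluster 7 decides nothing, and either could hold, as could a difference between 2 animals.

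Inhibitory receptor and exhaustion genes were lower in KO CD8 T-like cells (median -1.19), and these tests were written before their values were seen. Within subcluster 1 the median was -0.74, half-width 0.27. The bound, taken from the main median by a rule written beforehand, was -0.59. So a different mix of subclusters could account for part of the main median, and this is undecided. With cells thinned to 2000 UMIs the median was -1.08, half-width 0.28. Levels are already divided by all UMIs of the class, so thinning could hardly move the median through depth. Thinning also left out shallower cells, 408 to 387 in WT and 432 to 321 in KO. So this value does not decide whether lower depth in KO plays a part. The median was -0.75 with cells thinned only before clustering, where all UMIs of the cells were then summed, so it depends on which cells are in the class. After taking off the RNA of average macrophage-like cells, whose markers were lower too, it was -1.195, half-width 0.26, which argues against less of that RNA, while RNA of other cells was not tested.

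Type I interferon response genes were lower in both KO CD4 T-like classes, and these tests were written before their values were seen. In conventional CD4 T-like cells (median -1.32) the value within subcluster 4 was -0.60, half-width 0.16, with 10 of 42 higher and 32 lower. The bound, taken from the main median by the rule written beforehand, was -0.66. So subcluster mix could account for part of the main median, and how much is undecided. Without the 5% of cells highest in the list it was -1.11, half-width 0.21, and after taking off the RNA of average macrophage-like cells -1.35, half-width 0.14, which argues against a few extreme WT cells and less macrophage-like RNA as the whole source. With the stricter cell filter it was 0.011, Oasl1 was at 0.27 and Ccl4 at 1.08, so whether it holds depends on which cells are in the class. In regulatory T-like cells (median -0.61, bound -0.31) the value was -0.56, half-width 0.17, within subcluster 3, -0.53, half-width 0.17, without the highest 5% and -0.66, half-width 0.16, after taking off macrophage-like RNA, which argues against each, while RNA of other cells was not tested.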
